A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

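Labelled RNA from 8 samples of Saccharomyces cerevisiae was measured on 8 one-colour Agilent arrays of 1 slide, read in 1 scan. The groups came from the genotype in the sample labels: Δire1 (n = 3), SSZ1OEΔire1 (n = 2) and SSZ1OEΔire1Δscj1 (n = 3). Per the labels' protocols, cells grew in synthetic medium at 30 °C and 200 rpm to an OD600 between 0.2 and 0.3, RNA was column-purified, and 100 ng was primed with oligo-dT and transcribed with T7 polymerase into Cy3-labelled cRNA. Each array held 62976 spots, of which 61657 were non-control spots of 6616 probes, with 9 to 10 spots per probe.

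Spot intensity values were produced by the authors with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. Per the file headers the processed intensity is background-subtracted and spatially detrended, and it was not scaled between arrays. The median spot and local background intensities, used in an alternative, are uncorrected per the file headers. The last file, SSZ1OEΔire1Δscj1 replicate 3, had been saved again with values kept to 3 significant digits. A deposited value table of the same arrays holds log2 values per probe from the authors, and neither its scale nor its centring is stated. Set against the scanner values, its columns matched log2 processed signal minus the array's 75th percentile minus the probe's median over the arrays (r = 1.00 per array across probes, median absolute difference 0.00098 to 0.0039). The column medians of this deposited log2 table lay between −0.032 and 0.011. The file headers name an array design built on sacCer1. Files give no probe coordinates, so no positions are given.

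Values were the log2 processed signal, averaged over a probe's spots with outlier spots left out (1.10% to 1.57% of non-control spots), minus the array's 75th percentile over non-control probes. Probes with only outlier spots kept them. A probe counted as well above background on an array where more than 0.5 of its spots were, and it was tested if so on every array of at least 1 group. The brightest probe over all arrays stood for each of 6576 systematic names. For 39 names with several probes the largest disagreement in a comparison was 1.11 on the log2 scale (TC21605, SSZ1OEΔire1Δscj1 against SSZ1OEΔire1). Names were updated through a RefSeq gene table of assembly R64, used for symbols and for which genes neighbour each other: 5903 names matched, and 673 kept the name of the file. In all, 6240 genes were tested. Median values of negative control spots were 3.55 to 5.05 in slide row 1 and 9.49 to 14.4 in slide row 2. The lowest values counted as well above background were −8.31 to −7.22 relative to the 75th percentile.

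Differences were tested with limma 3.58.1 in R 4.3.3 (data.table package, version 1.17.8), with 3 group means over all 8 arrays, eBayes and Benjamini-Hochberg adjustment per comparison at 0.05. All tests were two-sided. For a gene well above background on no array of 1 group, the fold change is a bound: the mean of the other group against the mean, over the dim arrays, of the lowest signal counted as well above background or the probe's own signal where higher. The median gene SD was 0.13 in Δire1, 0.068 in SSZ1OEΔire1 and 0.10 in SSZ1OEΔire1Δscj1, and the median SE of a difference was 0.12, 0.10 and 0.12 for SSZ1OEΔire1 against Δire1, SSZ1OEΔire1Δscj1 against Δire1 and SSZ1OEΔire1Δscj1 against SSZ1OEΔire1. Principal components 1, 2 and 3 held 59.7%, 17.9% and 7.69% of the variance. The steps were tested on simulated data: of 50 genes per size among 6240, a 1.5-fold change was called in 70%, 70% and 60% for these comparisons in order, a 2-fold change in 90%, 98% and 88%, and a 4-fold change in 100%, 98% and 100%. Unchanged genes gave 10, 15 and 10 calls. The simulated noise was independent between genes, had the same spread in all groups and held no deviation of a whole array. These shares may therefore overstate what the real arrays recover.

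Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, for lists with at least 3 tested members. The 35 lists were Pdr1/Pdr3 targets, ribosome-associated chaperones, UPR targets, ER chaperones, ER-associated degradation, Hsf1 targets, Msn2/Msn4 stress genes, Yap1 oxidative stress genes, cell wall integrity, ergosterol, phospholipids, ribosome assembly, the proteasome, glycolysis, glucose-repressed genes, hexose transporters, respiration, the tricarboxylic acid cycle, Gcn4 amino acid genes, methionine and sulfur, phosphate, iron, nitrogen catabolite repression, purines and pyrimidines, marker genes, a-mating, alpha-mating, haploid and pheromone genes, meiosis, histones, G1/S, G2/M, translation factors, ribosomal proteins, and HAC1 alone, which was too small to test. Some genes lie in more than 1 list. The lists, groups, tests, rule for named genes and alternatives were fixed before the data were examined, except where said. That rule picked SSZ1, IRE1, SCJ1, HAC1 and KAR2, and per comparison the 10 largest rises and 10 largest falls among called genes whose groups do not overlap. It also picked up to 4 called members with the largest change from each list, or at most the largest member of a list with none called. Counts of named genes cover all genes so picked, of which the text gives only some. Overlap of calls between both comparisons against Δire1 was set beside 100 simulations. In these all arrays were independent noise without any change, and both comparisons shared the simulated controls.

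Alternatives were normexp background correction (offset 50), quantile normalization, median scaling, no filter on dim probes, probes well above background on all 8 arrays, the mean of a gene's probes, the authors' value table, an eBayes trend, array weights, a fit of only the 2 groups compared, slide row as a block, replicate number as a block, each array left out in turn, at least 2-fold changes, an adjusted p under 0.01, camera with an estimated correlation, and fry. Ranges of a list's adjusted p cover the alternatives tested with camera at the preset correlation. Scaling on 7 spike-in probes well above background on every array was chosen after seeing the data. Leaving out 1 of the 2 SSZ1OEΔire1 arrays assumes that the other varies like the other groups. Normexp was planned on mean spot signal and was run on median spot signal, the column the files hold. Array weights were estimated gene by gene after the default did not converge. After values had been seen, ARG5,6, DUR1,2 and ADE5,7 were respelled as ARG56, DUR12 and ADE57 so that they matched. The sign of a list's median, not camera's direction, was taken as its direction across alternatives, a choice made after reversals had been seen: of 2142 comparisons 111 then reversed against 68 by camera, and 10 against 1 among called lists. Genes with opposite effects were taken as those called in opposite directions against Δire1 and called in the test of the difference, a rule set after values had been seen. Of the genes this rule picked, 1 is not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.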

Results

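Transcript levels were measured across the genome of Saccharomyces cerevisiae in 3 strains that all lacked IRE1, the endoplasmic reticulum (ER) sensor of unfolded proteins that splices HAC1 mRNA. By its label, the reference strain carried the IRE1 deletion alone (Δire1, n = 3). A further strain also overexpressed SSZ1, which encodes an Hsp70-like protein that sits on ribosomes and is also known as Pdr13 (SSZ1OEΔire1, n = 2). The remaining strain combined both with deletion of SCJ1, which encodes a J-domain co-chaperone of the ER lumen (SSZ1OEΔire1Δscj1, n = 3). Cells were in early log phase in synthetic medium at 30 °C, and each sample was hybridised to 1 one-colour Agilent array of the same slide. The labels describe independent samples without saying that they were separate cultures, so p-values here measure the spread between these samples, which may be technical. Between 90.5% and 95.9% of the non-control spots of an array were well above background and 0 were saturated. The 75th percentile of signal lay between 9041 and 10016.5 on the SSZ1OEΔire1Δscj1 arrays. On the other arrays it lay between 5037 and 7152, so brightness cannot be told apart from that strain. The number of arrays limits the precision. Replicates differed per gene by a median of 0.096 on the log2 scale in SSZ1OEΔire1 and by 0.096 to 0.14 in SSZ1OEΔire1Δscj1. In Δire1, replicates 1 and 3 differed by 0.056, and replicate 2 differed from each of them by 0.20 to 0.21. Slide row 1 held both SSZ1OEΔire1 arrays with Δire1 replicates 1 and 2, and row 2 held Δire1 replicate 3 with all SSZ1OEΔire1Δscj1 arrays.

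The targeted genes were examined first. SSZ1 (YHR064C) stood at 5.84 ± 0.32 in SSZ1OEΔire1 (mean log2 signal relative to the array's 75th percentile ± SD, n = 2), at 5.37 ± 0.16 in SSZ1OEΔire1Δscj1 (n = 3) and at 2.97 ± 0.15 in Δire1 (n = 3). This was 7.30-fold higher in SSZ1OEΔire1 (log2 difference 2.87, SE 0.16, limma adjusted p = 0.000668) and 5.29-fold higher in SSZ1OEΔire1Δscj1 (2.40, SE 0.15, adjusted p = 0.00018) than in Δire1. The SSZ1 level of the 2 overexpressing strains was not told apart by the test (difference −0.47, SE 0.16, adjusted p = 0.0998), and it turned to 0.073 with quantile normalization. IRE1 (YHR079C) was not well above background on any of the 8 arrays. SCJ1 (YMR214W) stood at 0.52 ± 0.17 in Δire1 and at 0.88 ± 0.04 in SSZ1OEΔire1, a difference that did not pass the test (0.36, SE 0.15, adjusted p = 0.173). It was not well above background on any SSZ1OEΔire1Δscj1 array (measured mean −9.67 ± 0.25), at least 317-fold below Δire1 (adjusted p = 2.78e-08) and at least 406-fold below SSZ1OEΔire1 (adjusted p = 4.96e-08). Here and below, "at least" compares the bright group's mean with the lowest signal that counted as well above background on the dim arrays. HAC1, the transcription factor gene of the unfolded protein response (UPR), differed by 0.19 in SSZ1OEΔire1 (SE 0.12, adjusted p = 0.319) and by 0.20 in SSZ1OEΔire1Δscj1 (SE 0.10, adjusted p = 0.158), so no change was detected at this number of arrays.

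**Figure D1:**
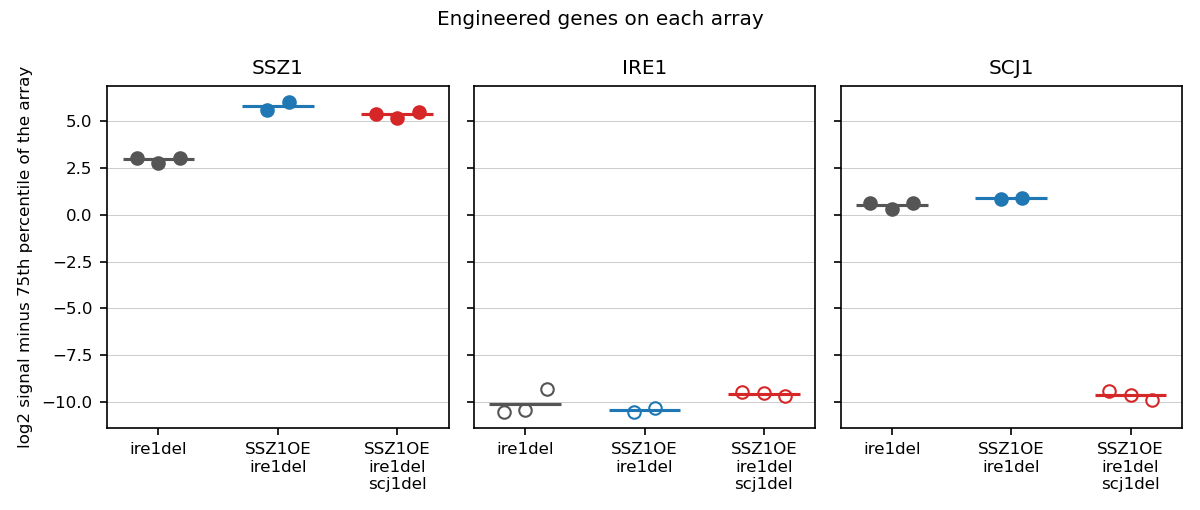
Log2 signal minus the array's 75th percentile (vertical axis) of SSZ1, IRE1 and SCJ1 on each of the 8 arrays, by strain; filled points were well above background, open points were not, and bars mark the group means. SSZ1 was higher on all 5 arrays of the overexpressing strains than on any Δire1 array, IRE1 was dim on every array, and SCJ1 was dim on the 3 SSZ1OEΔire1Δscj1 arrays alone.

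The comparison of SSZ1OEΔire1 with Δire1 asked what SSZ1 overexpression changes in cells without IRE1. Targets of Pdr1 and Pdr3, the factors of pleiotropic drug resistance, were higher, while PHO84, which encodes the high-affinity phosphate transporter, and the permease genes MEP2 and GAP1 were lower. With an estimated correlation camera called 0 lists here (3 at an unadjusted p under 0.05, lowest adjusted p = 0.146), and fry called 6. PDR5, encoding the major multidrug exporter, rose by 2.18 on the log2 scale (SE 0.09, limma adjusted p = 8.34e-05) and YGR035C, a gene of unknown function, by 3.30 (SE 0.31, adjusted p = 0.00288). PHO84 fell by 5.55 (SE 0.40, adjusted p = 0.00169), MEP2, an ammonium permease gene, by 2.68 (SE 0.28, adjusted p = 0.0037) and GAP1, the general amino acid permease gene, by 1.92 (SE 0.22, adjusted p = 0.0041). STE3, the receptor gene for a-factor, rose by 2.12 (SE 0.18, adjusted p = 0.00212), and the open reading frame YKL177W, which overlaps it, was at least 2.15-fold higher (adjusted p = 0.00169).

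Of 19 measured Pdr1/Pdr3 targets, 12 rose and 0 fell (14 rose adjusted over the list alone, median log2 difference 1.07, camera adjusted p = 4.19e-09). With an estimated correlation the list had adjusted p = 0.146. RSB1, a sphingoid base export gene, rose by 1.81 (SE 0.19). GRE2, a stress-induced reductase gene of the Yap1 list, rose by 2.34 (SE 0.26), but that list as a whole was not past the test (2 rose and 0 fell of 19, median 0.00086, adjusted p = 0.897). Glucose-repressed genes were higher (3 rose and 0 fell of 23, 4 adjusted over the list alone, median 0.39, or 0.21 without SSZ1OEΔire1 replicate 2, adjusted p = 0.00414, and adjusted p = 0.645 with an estimated correlation). Among them MAL32, a maltase gene, rose by 1.90 (SE 0.24) and CAT8, a regulator of gluconeogenesis, by 1.17 (SE 0.12). Hsf1 targets were higher (5 rose and 0 fell of 28, 7 adjusted over the list alone, median 0.28, adjusted p = 0.00316, and adjusted p = 0.645 with an estimated correlation). AHA1, which encodes an activator of Hsp90, rose by 1.09 (SE 0.11). Cell wall integrity genes (5 rose and 0 fell of 21, 7 adjusted over the list alone, median 0.32, adjusted p = 0.0272) passed the test. ER chaperones (3 rose and 0 fell of 16, 3 adjusted over the list alone, median 0.18, adjusted p = 0.0276) did as well. Both had adjusted p = 0.645 with an estimated correlation. Without SSZ1OEΔire1 replicate 2 neither passed (wall median 0.050, adjusted p = 0.344, ER adjusted p = 0.0698), nor without Δire1 replicate 2 (wall adjusted p = 0.146, ER median 0.11, adjusted p = 0.0804), and spike-in scaling ended the ER call (0.118). Over the alternatives at the preset correlation the adjusted p ranged from 5.54e-05 to 0.344 for the wall list and from 0.0101 to 0.118 for the ER list. KDX1, a kinase gene induced by wall stress, rose by 1.30 (SE 0.22). KAR2, the ER Hsp70 gene, rose by 0.59 (SE 0.08, adjusted p = 0.00676), a call that ended without SSZ1OEΔire1 replicate 2 (adjusted p = 0.0711) and with spike-in scaling, where it rose by 0.70 (adjusted p = 0.165, range over the alternatives 0.000856 to 0.165). The respiratory chain list was higher (3 rose and 0 fell of 38, 3 adjusted over the list alone, median 0.14, adjusted p = 0.00921, and adjusted p = 0.712 with an estimated correlation). Its call ended without SSZ1OEΔire1 replicate 1 (median 0.031, adjusted p = 0.859, range at the preset correlation 9.75e-08 to 0.859).

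Ribosome assembly factors were lower (0 rose and 34 fell of 65, 48 fell adjusted over the list alone, median −0.33, adjusted p = 2.79e-22, and adjusted p = 0.146 with an estimated correlation). RPF2, an assembly factor of the large subunit, differed by −0.67 (SE 0.08, adjusted p = 0.0053, range over the alternatives 0.000476 to 0.366, ending without SSZ1OEΔire1 replicate 2, 0.0643, and with spike-in scaling, −0.56). Genes of purine and pyrimidine synthesis were lower (0 rose and 11 fell of 25, 12 fell adjusted over the list alone, median −0.38, adjusted p = 3.6e-10, and adjusted p = 0.146 with an estimated correlation), among them ADE17, which fell by 1.22 (SE 0.15). Nitrogen catabolite-repressed genes (2 rose and 6 fell of 23, 2 and 8 adjusted over the list alone, median −0.42, adjusted p = 0.000293) and phosphate genes (0 rose and 6 fell of 18, 2 and 7 adjusted over the list alone, median −0.15, adjusted p = 0.00255) were lower. Their values were adjusted p = 0.645 and adjusted p = 0.481 with an estimated correlation. DUR12, spelled DUR1,2 elsewhere and encoding urea amidolyase, fell by 1.46 (SE 0.16). Without Δire1 replicate 2 the nitrogen median was −0.21, and without SSZ1OEΔire1 replicate 2 the phosphate median was −0.30. The histone list (0 rose and 3 fell of 9, 8 fell adjusted over the list alone, median −0.40, adjusted p = 5.82e-05) had adjusted p = 0.481 with an estimated correlation. Phospholipid genes (0 rose and 4 fell of 17, 1 rose and 9 fell adjusted over the list alone, median −0.30, adjusted p = 5.82e-05) were lower, as were ergosterol genes (0 rose and 2 fell of 25, 5 fell adjusted over the list alone, median −0.28, or −0.17 without SSZ1OEΔire1 replicate 2, adjusted p = 5.5e-06). Translation factors (0 rose and 3 fell of 32, 3 fell adjusted over the list alone, median −0.14, adjusted p = 5.82e-05) were lower. These 3 lists had adjusted p = 0.645 with an estimated correlation. The Gcn4 amino acid list was lower (1 rose and 3 fell of 43, 1 and 2 adjusted over the list alone, median −0.14, adjusted p = 0.00121, and adjusted p = 0.749 with an estimated correlation). LYS9, of lysine synthesis, fell by 0.99 (SE 0.11). The G1/S list was lower (0 rose and 2 fell of 17, 1 and 2 adjusted over the list alone, median −0.18, or −0.12 without Δire1 replicate 1, adjusted p = 0.00979, and adjusted p = 0.645 with an estimated correlation). Left-out arrays ended some of these calls: the Gcn4 list without SSZ1OEΔire1 replicate 2 (median −0.030, adjusted p = 0.35, range at the preset correlation 1.35e-07 to 0.35) and the G1/S list without SSZ1OEΔire1 replicate 1 (0.126, range at the preset correlation 0.000394 to 0.126). Quantile normalization also ended the Gcn4 call (0.0591).

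The other lists did not pass in this comparison. UPR targets (4 rose, 0 fell of 38, median 0.13, adjusted p = 0.0804) and ER-associated degradation (2 rose, 0 fell of 19, median 0.12, adjusted p = 0.209) were among them. So were general stress genes under Msn2/Msn4 (3 rose, 0 fell of 29, median 0.22, adjusted p = 0.0804) and the proteasome (2 rose, 0 fell of 33, median 0.074, adjusted p = 0.0745). Of carbon metabolism these were glycolysis (0 of 20 called by limma, 3 at an unadjusted p under 0.05, median −0.12, adjusted p = 0.111) and hexose transporters (4 rose, 0 fell of 14, median 0.18, adjusted p = 0.115), with the tricarboxylic acid cycle (0 of 17 called, 4 unadjusted, median 0.16, adjusted p = 0.121). HXT10, a hexose transporter gene, rose by 1.49 (SE 0.16). The methionine list (0 rose, 1 fell of 23, median −0.12, adjusted p = 0.391) and the iron list (2 rose, 1 fell of 24, median −0.15, adjusted p = 0.28) did not pass either. Nor did the marker genes of laboratory strains (0 of 8 called, 3 unadjusted, median −0.19, adjusted p = 0.493). Of these LEU2 stood at 2.43 and 2.42 in SSZ1OEΔire1, while Δire1 replicates 1 to 3 were split (0.48, −0.021 and 2.73). Of the cell-type lists, a-mating genes (0 of 7 called, 1 unadjusted, median −0.029, adjusted p = 0.812) and alpha-mating genes (1 rose, 0 fell of 5, median −0.14, adjusted p = 0.864) did not pass. Nor did haploid and pheromone genes (2 rose, 2 fell of 16, median 0.036, adjusted p = 0.998) or meiosis genes (3 rose, 1 fell of 18, median 0.25, adjusted p = 0.111). The G2/M list (1 rose, 1 fell of 19, median −0.12, adjusted p = 0.299), the ribosome-associated chaperones (2 rose, 0 fell of 7, median −0.039, adjusted p = 0.998) and the ribosomal proteins (2 rose, 0 fell of 136, median −0.025, adjusted p = 0.566) completed the set. The median's sign turned with spike-in scaling for the ribosomal proteins, ribosome-associated chaperones and a-mating genes, with quantile normalization for meiosis genes, and with quantile and median scaling for the Yap1 and haploid lists. Median, mean and test differed in sign for the ribosome-associated chaperones, the Yap1, alpha-mating and haploid lists and the ribosomal proteins.

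In all, 713 of 6240 genes passed limma's test, of which 469 rose (65.8%) and 244 fell, with 182 rising and 23 falling at least 2-fold. The direction went with signal level: of the dimmest 624 genes 84 rose and 9 fell (median 0.24). Of the brightest 624 genes 24 rose and 37 fell (median −0.055). The cause of this was not tested, so the excess of rises may be technical. The arrays of both strains did not overlap for 2896 genes (46.4%, against 20% by chance). The number of calls rested on single arrays: it was 60 without SSZ1OEΔire1 replicate 2, 280 without SSZ1OEΔire1 replicate 1, 342, 1507 and 252 without Δire1 replicates 1, 2 and 3, and 252 with slide row as a block, which leaves only row 1 to bear on this comparison. The split moved to 339 rises and 376 falls with quantile normalization, to 371 and 347 with median scaling, and to 184 and 21 with spike-in scaling, which moved the median of all genes to 0.13.

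The comparison of SSZ1OEΔire1Δscj1 with Δire1 asked what SSZ1 overexpression and loss of SCJ1 do together in cells without IRE1. Drug resistance targets were again higher, along with cell wall and glucose-repressed genes and several alpha-mating genes, while amino acid, purine, ribosomal protein, G2/M and a-mating genes were lower relative to the array's 75th percentile. With an estimated correlation camera called 0 lists here (3 at an unadjusted p under 0.05, lowest adjusted p = 0.206), and fry called 21. PDR5 rose by 2.73 (SE 0.08, limma adjusted p = 3.4e-06), RTA1, a lipid-translocating family gene, by 4.09 (SE 0.34, adjusted p = 0.000483) and STE3 by 3.07 (SE 0.16, adjusted p = 0.000104). GSC2, encoding a glucan synthase subunit of stressed walls, rose by 2.34 (SE 0.23, adjusted p = 0.000819). PHO84 fell by 5.18 (SE 0.36, adjusted p = 0.000401), MEP2 by 2.80 (SE 0.25, adjusted p = 0.000577), and HXT7, a high-affinity hexose transporter gene whose sequence is nearly that of HXT6, by 2.17 (SE 0.37, adjusted p = 0.00489). YFR057W, a gene of unknown function, was at least 7.60-fold higher (adjusted p = 0.00409).

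Of the Pdr1/Pdr3 targets, 18 of 19 rose and 0 fell (18 adjusted over the list alone, median 1.28, camera adjusted p = 1.18e-11, and adjusted p = 0.206 with an estimated correlation). ICT1, a lysophosphatidic acid acyltransferase gene, rose by 3.02 (SE 0.16) and CIS1 by 2.92 (SE 0.37). Cell wall integrity genes were higher (14 rose and 1 fell of 21, 15 and 1 adjusted over the list alone, median 0.89, adjusted p = 1.13e-05, and adjusted p = 0.327 with an estimated correlation), among them PIR3, a wall glycoprotein gene (2.45, SE 0.44), and PRM5 (1.84, SE 0.15). Glucose-repressed genes were higher (14 rose and 2 fell of 23, 18 and 2 adjusted over the list alone, median 0.81, adjusted p = 0.00065, and adjusted p = 0.461 with an estimated correlation). CAT8 rose by 1.72 (SE 0.10), while HXT6 and HXT7 were the members that fell (−1.99, SE 0.36, for HXT6). The proteasome list was higher (5 rose and 0 fell of 33, 1 adjusted over the list alone, median 0.15, adjusted p = 0.00476, and adjusted p = 0.327 with an estimated correlation), a call that ended with median scaling (0.0936) and with spike-in scaling (0.0658, range at the preset correlation 4.62e-07 to 0.0936). RPN4, the proteasome regulator gene, rose by 1.24 (SE 0.14).

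Of 5 alpha-mating genes 3 rose and 0 fell (3 adjusted over the list alone, median 1.05, adjusted p = 0.0306, and adjusted p = 0.327 with an estimated correlation), with MF(ALPHA)1, a pheromone gene, rising by 2.08 (SE 0.36) and AFB1, a barrier gene for a-factor, by 1.05 (SE 0.09). The a-mating list went the other way (0 rose and 6 fell of 7, 6 fell adjusted over the list alone, median −0.72, adjusted p = 0.00179, and adjusted p = 0.327 with an estimated correlation). AGA2, an a-agglutinin gene, fell by 0.78 (SE 0.10, adjusted p = 0.00184, range over the alternatives 0.000312 to 0.205, ending with spike-in scaling, −0.36). Meiosis genes were higher (10 rose and 1 fell of 18, 10 and 1 adjusted over the list alone, median 0.59, adjusted p = 0.00688, and adjusted p = 0.327 with an estimated correlation), among them NDT80, the mid-sporulation regulator gene, which rose by 1.18 (SE 0.19). The alpha list did not pass without SSZ1OEΔire1Δscj1 replicate 2 (adjusted p = 0.0671, range at the preset correlation 0.00462 to 0.0671), and with quantile normalization neither it (0.0533) nor the meiosis list (0.0506, range at the preset correlation 0.00108 to 0.0506) did. The haploid and pheromone list did not pass (4 rose and 7 fell of 16, median −0.11, turning to 0.31 with spike-in scaling, adjusted p = 0.426).

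Amino acid genes under Gcn4 were lower (0 rose and 37 fell of 43, 38 fell adjusted over the list alone, median −0.59, adjusted p = 9.46e-13), among them LYS20 of lysine synthesis (−1.67, SE 0.14), HIS4 of histidine synthesis (−1.10, SE 0.19), and ARG4 of arginine synthesis (−1.18, SE 0.21). Its value was adjusted p = 0.327 with an estimated correlation, as were those of all falling lists below except ribosome assembly (0.226), purine and pyrimidine synthesis (0.206) and ergosterol (0.539). Purine and pyrimidine genes fell in 20 of 25 cases and rose in 0 (1 rose and 21 fell adjusted over the list alone, median −0.50, adjusted p = 7.1e-09), with GCV2, a glycine cleavage gene, falling by 1.25 (SE 0.14). The methionine list was lower (1 rose and 9 fell of 23, likewise adjusted over the list alone, median −0.40, turning to 0.021 with spike-in scaling, adjusted p = 0.00179), with MET6, methionine synthase, falling by 1.38 (SE 0.15). Genes of the G2/M list were lower (0 rose and 14 fell of 19, 15 fell adjusted over the list alone, median −0.67, adjusted p = 9.12e-07), among them AMN1 (−1.01, SE 0.13) and DSE4, a daughter-cell glucanase gene (−0.95, SE 0.17).

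The translation machinery was lower relative to the array's 75th percentile. Of 136 ribosomal protein genes 0 rose and 93 fell (102 fell adjusted over the list alone, median −0.44, and −0.11 with quantile normalization or −0.020 with spike-in scaling, adjusted p = 3.26e-21, and adjusted p = 0.327 with an estimated correlation). Translation factors (0 rose and 24 fell of 32, 25 fell adjusted over the list alone, median −0.39, turning to 0.025 with spike-in scaling, adjusted p = 4.03e-09) were lower. So were ribosome assembly factors (0 rose and 46 fell of 65, 52 fell adjusted over the list alone, median −0.34, turning to 0.071 with spike-in scaling, adjusted p = 6.75e-15). Spike-in scaling, chosen after seeing the data, moved the median of all genes to 0.43, and relative to that median the ribosomal proteins lay at −0.46, translation factors at −0.41 and ribosome assembly factors at −0.36. This scaling shifts all genes alike, so by construction these relative values are the same without it and test nothing further. The ribosome-associated chaperones did not pass (0 rose and 4 fell of 7, median −0.36, turning to 0.059 with spike-in scaling, adjusted p = 0.0672). Glycolysis genes were lower (2 rose and 14 fell of 20, 2 and 15 adjusted over the list alone, median −0.48, adjusted p = 3.68e-05), but not with quantile normalization (median −0.067, adjusted p = 0.626, range at the preset correlation 8.74e-07 to 0.626). PDC6, a minor pyruvate decarboxylase gene of that list, rose by 1.81 (SE 0.23). A lower median that spike-in scaling turned was that of phospholipid genes (0 rose and 10 fell of 17, 13 fell adjusted over the list alone, median −0.35, turned to 0.065, adjusted p = 5.37e-06). Another was that of ergosterol genes (1 rose and 8 fell of 25, 1 and 9 adjusted over the list alone, median −0.21, turned to 0.21, adjusted p = 0.00163). It also turned that of histones (0 rose and 8 fell of 9, 8 fell adjusted over the list alone, median −0.31, turned to 0.10, adjusted p = 0.000496). The same held for phosphate genes (2 rose and 9 fell of 18, 3 and 9 adjusted over the list alone, median −0.24, turned to 0.17, adjusted p = 0.0108). Relative to the median of all genes, these 4 lists lay at −0.37, −0.23, −0.33 and −0.26, which that scaling leaves unchanged by construction. With quantile normalization the ergosterol (0.363, range at the preset correlation 4.91e-05 to 0.363) and histone (0.448, range at the preset correlation 0.000312 to 0.448) calls ended, and without Δire1 replicate 2 (0.0713) and with array weights (0.0742) the phosphate call did (range at the preset correlation 1.65e-05 to 0.0742).

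The remaining lists did not pass. They were UPR targets (6 rose, 2 fell of 38, median 0.058, adjusted p = 0.535), ER chaperones (4 rose, 0 fell of 16, median 0.042, adjusted p = 0.426) and ER-associated degradation (6 rose, 0 fell of 19, median 0.13, adjusted p = 0.167). DER1, encoding a component of that degradation pathway, rose by 0.70 (SE 0.10), ROT1, an ER chaperone gene, rose by 0.57 (SE 0.07), and KAR2 differed by −0.15 (SE 0.07, adjusted p = 0.128), turning to 0.27 with spike-in scaling. Hsf1 targets (2 rose, 5 fell of 28, median −0.021, adjusted p = 0.375) and Msn2/Msn4 stress genes (7 rose, 0 fell of 29, median 0.24, adjusted p = 0.0512) did not pass. Neither did the Yap1 list (4 rose, 3 fell of 19, median −0.023, adjusted p = 0.547), and spike-in scaling turned the Hsf1 and Yap1 medians. Hexose transporters (5 rose, 3 fell of 14, median 0.15, adjusted p = 0.304) and respiration (2 rose, 0 fell of 38, median 0.034, adjusted p = 0.699) did not. The tricarboxylic acid cycle (3 rose, 0 fell of 17, median 0.0081, adjusted p = 0.655) did not either, nor did iron genes (6 rose, 3 fell of 24, median 0.22, adjusted p = 0.235). Nitrogen genes (2 rose, 7 fell of 23, median −0.12, adjusted p = 0.0682), marker genes (1 rose, 4 fell of 8, median −0.41, adjusted p = 0.198) and G1/S genes (1 rose, 5 fell of 17, median −0.056, adjusted p = 0.302) did not pass, and spike-in scaling turned all 3 medians. Median scaling turned the medians of UPR targets, ER chaperones, respiration and the tricarboxylic acid cycle, and quantile normalization those of ER chaperones and Hsf1 targets. Median, mean and test differed in sign for the Hsf1, Yap1 and haploid lists.

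In all, 2390 of 6240 genes passed limma's test: 1333 rose (55.8%) and 1057 fell, with 297 rising and 46 falling at least 2-fold. Direction again went with signal level: of the dimmest 624 genes 153 rose and 35 fell, and of the brightest 624 genes 30 rose and 306 fell. The arrays of both strains did not overlap for 3159 genes (50.6%, against 10% by chance). The count was 1440 without Δire1 replicate 3, 1560 without SSZ1OEΔire1Δscj1 replicate 1 and 1065 with slide row as a block, where row 2 alone, with 1 Δire1 array, bears on this comparison. The split was 943 rises and 1381 falls with quantile normalization, 989 and 1573 with median scaling, and 2023 and 43 with spike-in scaling.

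**Figure D2:**
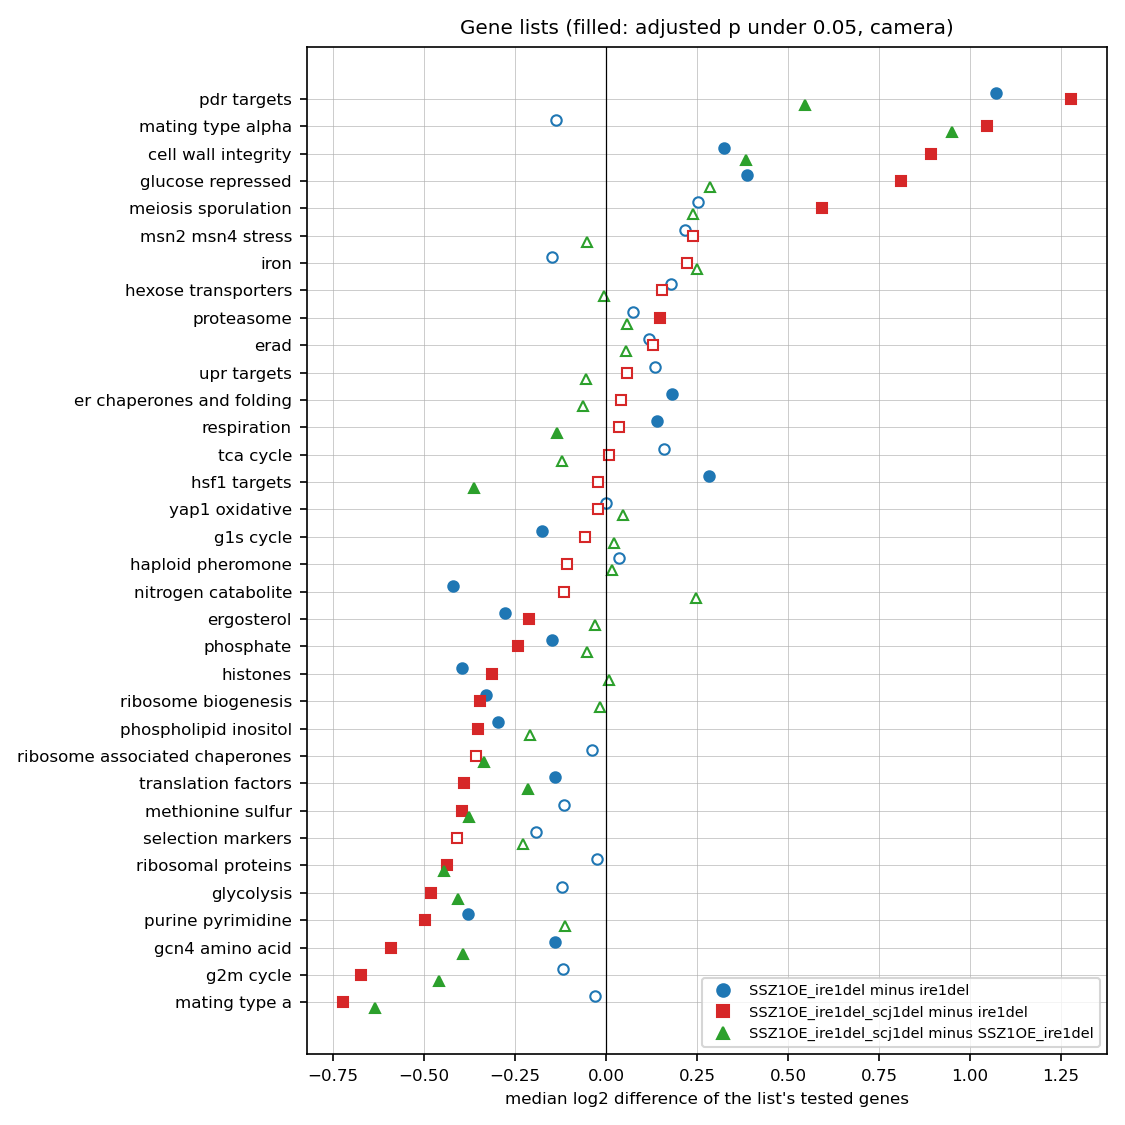
Median log2 difference of the measured members of each gene list (horizontal axis) in the 3 comparisons; filled points passed camera's test at an adjusted p under 0.05, open points did not. Pdr1/Pdr3 targets lay highest against Δire1 in both overexpressing strains (1.07 and 1.28); the ribosomal proteins lay near 0 in SSZ1OEΔire1 (−0.025, turning to 0.081 with spike-in scaling) and at −0.44 in SSZ1OEΔire1Δscj1 (−0.020 with spike-in scaling).

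The comparison of SSZ1OEΔire1Δscj1 with SSZ1OEΔire1 asked what loss of SCJ1 adds in overexpressing cells, and it is also the test of the difference between the foregoing comparisons. Wall, drug resistance and alpha-mating genes were higher and amino acid, Hsf1, a-mating and ribosomal protein genes were lower in the strain without SCJ1. With an estimated correlation camera called 0 lists here (2 at an unadjusted p under 0.05, lowest adjusted p = 0.704), and fry called 7. GSC2 rose by 2.78 (SE 0.26, limma adjusted p = 0.00577), RTA1 by 2.74 (SE 0.38, adjusted p = 0.0112) and AFB1 by 1.20 (SE 0.10, adjusted p = 0.00492). AHA1 fell by 1.18 (SE 0.11, adjusted p = 0.00559) and KAR2 by 0.74 (SE 0.08, adjusted p = 0.00864). Of 98 calls among the named genes other than SCJ1, 97 did not pass without SSZ1OEΔire1 replicate 1 (adjusted p from 0.018, for AHA1, which stayed past the test, to 0.312). With slide row as a block, where these strains lie in different rows and are joined through Δire1 alone, the adjusted p of all 98 lay between 0.131 and 0.548, and SCJ1 was the only named gene called under every alternative that tested it, which leaves out that of probes well above background on all 8 arrays.

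Pdr1/Pdr3 targets were higher still than in SSZ1OEΔire1 (9 rose and 0 fell of 19, 12 rose adjusted over the list alone, median 0.55, camera adjusted p = 7.76e-06). Cell wall integrity genes were higher (9 rose and 1 fell of 21, 10 and 1 adjusted over the list alone, median 0.38, or 0.18 without SSZ1OEΔire1 replicate 1, adjusted p = 0.000384), among them NCW2, a wall protein gene (1.97, SE 0.26), and YPS1, a yapsin protease gene (1.18, SE 0.13). Of the alpha-mating genes 3 of 5 rose and 0 fell (3 adjusted over the list alone, median 0.95, adjusted p = 0.00603), and MF(ALPHA)1 rose by 1.65 (SE 0.40, adjusted p = 0.0414). These 3 lists, and the falling lists except where said, had adjusted p = 0.704 with an estimated correlation.

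Ribosomal protein genes were lower (0 rose and 72 fell of 136, 114 fell adjusted over the list alone, median −0.44, adjusted p = 5.52e-29, and adjusted p = 0.704 with an estimated correlation). Spike-in scaling moved the median of all genes to 0.31. It shifts all genes alike, so by construction the ribosomal proteins stayed at −0.44 relative to all genes. With quantile normalization they lay at −0.098 relative to all genes. RPL29 fell by 0.80 (SE 0.12) and RPS14B by 0.67 (SE 0.09). Gcn4 amino acid genes were lower (0 rose and 13 fell of 43, 26 fell adjusted over the list alone, median −0.39, adjusted p = 8.62e-09), among them ARG3 (−1.18, SE 0.24) and ARG4 (−1.17, SE 0.23) of arginine synthesis. The methionine list was lower too (1 rose and 6 fell of 23, 3 and 10 adjusted over the list alone, median −0.38, adjusted p = 0.013). MMP1, the S-methylmethionine permease gene, fell by 1.16 (SE 0.14). Hsf1 targets were lower (0 rose and 9 fell of 28, 12 fell adjusted over the list alone, median −0.36, adjusted p = 0.000384), including the mitochondrial chaperone genes HSP60 (−0.88, SE 0.14) and SSC1 (−0.69, SE 0.09). The a-mating list was lower (0 rose and 4 fell of 7, 5 fell adjusted over the list alone, median −0.64, adjusted p = 0.00046), with BAR1, the alpha-factor protease gene, falling by 0.98 (SE 0.16). The G2/M list was lower (0 rose and 8 fell of 19, 1 and 14 adjusted over the list alone, median −0.46, adjusted p = 3.84e-07), with EGT2, a cell separation gene, falling by 1.03 (SE 0.14). Ribosome-associated chaperones were lower (0 rose and 2 fell of 7, 4 fell adjusted over the list alone, median −0.33, adjusted p = 0.00603), among them ZUO1, which encodes the partner of Ssz1 (−0.41, SE 0.09). Translation factors (0 rose and 5 fell of 32, 9 fell adjusted over the list alone, median −0.21, turning to 0.098 with spike-in scaling, adjusted p = 0.000384, and adjusted p = 0.765 with an estimated correlation) were lower. So were glycolysis genes (1 rose and 4 fell of 20, 1 and 12 adjusted over the list alone, median −0.41, turning to 0.024 with quantile normalization, adjusted p = 0.000384). The respiration list was lower (0 rose and 1 fell of 38, likewise adjusted over the list alone, median −0.13, turning to 0.18 with spike-in scaling, adjusted p = 0.0245, and adjusted p = 0.896 with an estimated correlation), with CYC7, a cytochrome c gene, falling by 1.60 (SE 0.19). That call ended without SSZ1OEΔire1 replicate 1 (median −0.0066, adjusted p = 0.916) and without SSZ1OEΔire1Δscj1 replicate 3 (0.1, range at the preset correlation 1.05e-05 to 0.916). It also ended with normexp (0.165) and with slide row as a block (0.159). Quantile normalization ended the calls of respiration (0.364), glycolysis (0.714, range at the preset correlation 0.000114 to 0.714), translation factors (0.714, range at the preset correlation 4.31e-05 to 0.714) and the ribosome-associated chaperones (0.23, range at the preset correlation 0.00237 to 0.23).

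The other lists did not pass here. They were UPR targets (2 rose, 3 fell of 38, median −0.056, adjusted p = 0.387), ER chaperones (1 rose, 2 fell of 16, median −0.064, adjusted p = 0.389) and ER-associated degradation (1 rose, 1 fell of 19, median 0.056, adjusted p = 0.754). Stress genes under Msn2/Msn4 (3 rose, 1 fell of 29, median −0.053, adjusted p = 0.879) and the Yap1 list (1 rose, 2 fell of 19, median 0.047, adjusted p = 0.707) did not pass. Neither did the proteasome (0 of 33 called by limma, 4 at an unadjusted p under 0.05, median 0.057, adjusted p = 0.199). Ergosterol genes (3 rose, 0 fell of 25, median −0.031, adjusted p = 0.707), phospholipid genes (0 rose, 3 fell of 17, median −0.21, adjusted p = 0.199) and ribosome assembly factors (0 rose, 1 fell of 65, median −0.016, adjusted p = 0.967) did not. Glucose-repressed genes (3 rose, 2 fell of 23, median 0.29, adjusted p = 0.199) and hexose transporters (1 rose, 2 fell of 14, median −0.0056, or 0.019 with a dim member at its bound, adjusted p = 0.878) did not. The tricarboxylic acid cycle (1 rose, 0 fell of 17, median −0.12, adjusted p = 0.41) did not either, although CIT2, a peroxisomal citrate synthase gene, rose by 2.04 (SE 0.36). Phosphate (0 of 18 called, 4 unadjusted, median −0.052, adjusted p = 0.879) and iron genes (1 rose, 0 fell of 24, median 0.25, adjusted p = 0.0557) did not pass, nor did nitrogen (2 rose, 1 fell of 23, median 0.25, adjusted p = 0.226) or purine and pyrimidine genes (0 rose, 2 fell of 25, median −0.11, adjusted p = 0.382). Marker genes (0 of 8 called, 2 unadjusted, median −0.23, adjusted p = 0.357) and haploid genes (1 rose, 2 fell of 16, median 0.016, adjusted p = 0.755) did not pass. Meiosis genes (1 rose, 1 fell of 18, median 0.24, adjusted p = 0.112), histones (0 of 9 called, 0 unadjusted, median 0.0068, adjusted p = 0.879) and G1/S genes (2 rose, 1 fell of 17, median 0.022, adjusted p = 0.41) completed the set. Spike-in scaling turned the medians of UPR targets, ER chaperones, Msn2/Msn4, ergosterol, phospholipid, ribosome assembly, hexose transporter, tricarboxylic acid, phosphate, purine and marker genes. Quantile normalization turned those of the Yap1, ergosterol, phospholipid and ribosome assembly lists, and median scaling those of the haploid, histone and G1/S lists. Median, mean and test differed in sign for the Msn2/Msn4, Yap1, ergosterol, ribosome assembly, phosphate, haploid and histone lists.

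In all, 743 of 6240 genes passed limma's test: 393 rose (52.9%) and 350 fell, with 89 rising and 38 falling at least 2-fold. Of the brightest 624 genes 16 rose and 126 fell, and of the dimmest 624 genes 31 rose and 20 fell. The arrays of both strains did not overlap for 3682 genes (59.0%, against 20% by chance). The count was 3 and 221 without SSZ1OEΔire1 replicates 1 and 2. It was 1528 and 413 without Δire1 replicates 2 and 3, 127 and 272 without SSZ1OEΔire1Δscj1 replicates 1 and 2, and 2 with slide row as a block. The split was 423 rises and 650 falls with normexp background correction and 150 and 11 with spike-in scaling.

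**Figure D3:**
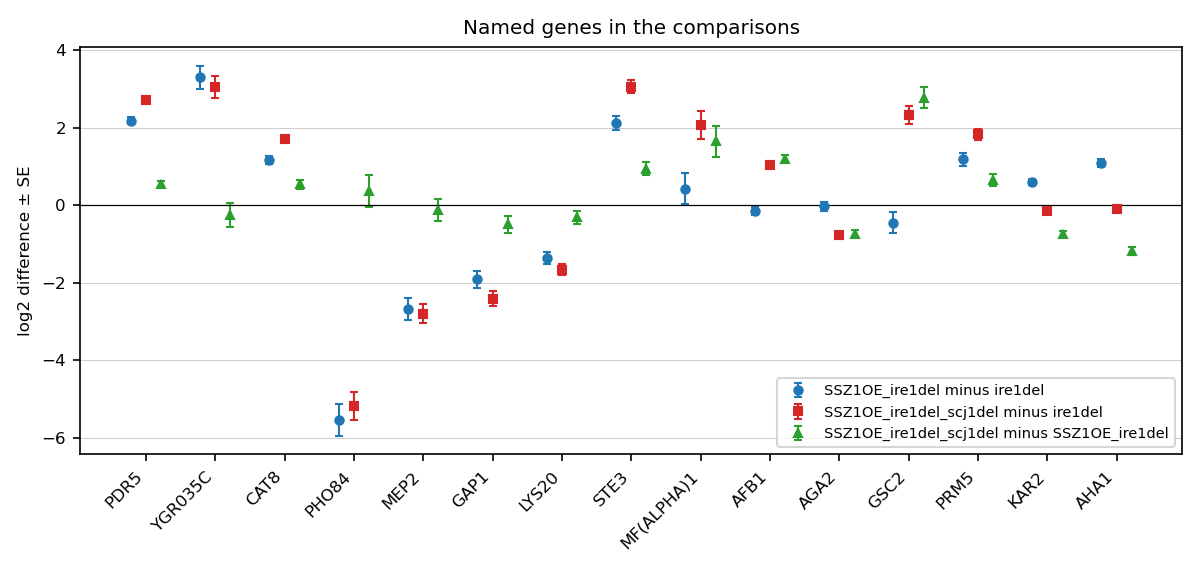
Log2 difference (vertical axis) of 15 named genes (horizontal axis) in the 3 comparisons, with bars of 1 standard error. PDR5, CAT8 and STE3 lay above 0 and PHO84, MEP2, GAP1 and LYS20 below 0 against Δire1 in both overexpressing strains, whereas KAR2 and AHA1 lay above 0 in SSZ1OEΔire1 against Δire1 and below 0 in SSZ1OEΔire1Δscj1 against SSZ1OEΔire1 (KAR2 in SSZ1OEΔire1Δscj1 against Δire1 turned from −0.15 to 0.27 with spike-in scaling).

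Both overexpressing strains were compared with the same 3 Δire1 arrays, and the shared part of these comparisons was examined. PDR5, YGR035C, CAT8, STE3 and GRE2 rose in both, and PHO84, MEP2, GAP1 and DUR12 fell in both. Together, 349 genes rose in both and 185 fell in both, where independent lists would share 100.2 and 41.3. In 100 simulations all arrays were independent noise without any change, with simulated controls shared by both comparisons. These shared 0 calls at most, which follows from the absence of any change and does not bear on the counts found. Of the genes called up in SSZ1OEΔire1, 74.4% also rose in SSZ1OEΔire1Δscj1, and 75.8% of those called down also fell, while 6 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 differences had r = 0.673 against a simulated mean of 0.446, and a covariance of 0.153 against a simulated 0.0111. The simulated noise held no correlation between genes and no deviation of a whole array, so it may understate what shared controls give. With 3 control arrays the controls could not be split with at least 2 in each part, so part of the excess may come from the shared controls. Shared rises ranged from 40 without SSZ1OEΔire1 replicate 2 to 739 without Δire1 replicate 2, with 190 without SSZ1OEΔire1 replicate 1, 187 and 135 without Δire1 replicates 1 and 3 and 230 without SSZ1OEΔire1Δscj1 replicate 1. The shared falls were 9, 442, 67, 71, 55 and 106 without those arrays in the same order, and 122 without SSZ1OEΔire1Δscj1 replicate 3.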

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

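The tests of this part were planned, and the rule that picked the genes below was set after the result was seen. The genes below differed between groups: each was called in opposite directions in SSZ1OEΔire1 and SSZ1OEΔire1Δscj1 against Δire1, and the difference between these effects also passed limma's test. PRM4, a pheromone-regulated gene, was lower in SSZ1OEΔire1 (−1.02) and higher in SSZ1OEΔire1Δscj1 (1.29), a difference of 2.31 (SE 0.23, adjusted p = 0.00795). RCF3, which encodes a protein of respiratory supercomplexes, went the same way (−0.35 and 0.31, difference 0.66, SE 0.088, adjusted p = 0.0109). ZEO1, a gene of cell wall signalling, was higher in SSZ1OEΔire1 (0.92) and lower in SSZ1OEΔire1Δscj1 (−0.70), a difference of −1.62 (SE 0.21, adjusted p = 0.0101). HSC82, a cytosolic Hsp90 gene of the Hsf1 list, did likewise (0.36 and −0.28, difference −0.65, SE 0.091, adjusted p = 0.0112), as did KTI11, a gene of diphthamide synthesis (0.40 and −0.27, difference −0.68, SE 0.073, adjusted p = 0.00864). None of these differences passed without SSZ1OEΔire1 replicate 1, where SCJ1, AHA1 and ANS1 alone were called, or with slide row as a block, where SCJ1 and ANS1 alone were called. Spike-in scaling shifts all genes by 0.42 in SSZ1OEΔire1Δscj1 against Δire1. That is more than the falls of HSC82 and KTI11 there, so with it these genes were not lower than in Δire1.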

How the results depend on the processing

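The alternatives were planned, except spike-in scaling, which was chosen after seeing the data, and the pairing below was checked once. Most calls kept their direction. Whether a gene was called depended most on single arrays, slide row and scaling, and whether a list was called depended most on the list test. A gene or list counts once per comparison here, and SSZ1 and SCJ1 are left out where engineered to differ. Of genes named by the rule, 81 of 334 called and 3 of 14 uncalled kept direction and call under every alternative. So did 0 of 48 lists called by camera and 3 of 54 uncalled lists. Camera with an estimated correlation by itself ended all 48 list calls. Without single arrays, 78 of 98 gene calls of SSZ1OEΔire1 against Δire1, 30 of 138 of SSZ1OEΔire1Δscj1 against Δire1 and 97 of 98 of SSZ1OEΔire1Δscj1 against SSZ1OEΔire1 ended at least once, as did 5 of 16, 2 of 19 and 1 of 13 list calls. Of the 334 gene calls, 4 ended with normexp, 49 with quantile normalization, 20 with median scaling, 18 without the filter, 1 with the mean of a gene's probes, 1 with the authors' value table, 2 with a trend, 0 with array weights, 54 in a fit of only the 2 groups, 173 with slide row as a block and 168 with spike-in scaling. Of the 48 list calls, 10 ended with quantile normalization, 4 with array weights and 17 with fry. With array weights these were the wall (adjusted p = 0.0993) and ER chaperone (0.0511) lists in SSZ1OEΔire1 against Δire1 and the alpha-mating (0.0589) and phosphate (0.0742) lists in SSZ1OEΔire1Δscj1 against Δire1. With spike-in scaling the ER chaperone list of the former (0.118) and the proteasome list of the latter (0.0658) did not pass, and 9 other lists passed camera with medians of opposite sign. Dim genes set the limit of measurement, since a signal under −7.22 to −8.31 relative to the 75th percentile cannot be told from background.

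With an estimated correlation camera called 0 lists in each comparison, where 3, 3 and 2 had an unadjusted p under 0.05, and fry called 6, 21 and 7. This setting replaces the preset correlation by 1 estimated per list. In SSZ1OEΔire1 against Δire1 the 713 calls became 2402 with array weights, 384 in a fit of only the 2 groups, 252 with slide row as a block, 205 with spike-in scaling, 205 at 2-fold or more and 134 at an adjusted p under 0.01, and ranged from 60 to 1507 without single arrays. In SSZ1OEΔire1Δscj1 against Δire1 the 2390 calls became 3822 with array weights, 1065 with slide row as a block, 343 at 2-fold or more and 1148 at the stricter threshold, and ranged from 1440 to 3165 without single arrays. In SSZ1OEΔire1Δscj1 against SSZ1OEΔire1 the 743 calls became 1637 with array weights, 2 with slide row as a block (SCJ1 and ANS1), 161 with spike-in scaling, 127 at 2-fold or more and 48 at the stricter threshold. They ranged from 3 (SCJ1, AHA1 and ANS1) to 1528 without single arrays. Shared rises became 223 with quantile normalization, 1055 with array weights, 189 in fits of 2 groups, 131 with slide row as a block and 169 with spike-in scaling, and shared falls 763 with array weights, 85 in fits of 2 groups, 37 with slide row as a block and 11 with spike-in scaling. Without single arrays they ranged from 40 to 739 and from 9 to 442. Stricter thresholds call fewer genes by construction. With slide row as a block, SSZ1OEΔire1Δscj1 meets SSZ1OEΔire1 only through the Δire1 arrays, since these strains lay in different rows. Of the other changes the cause was not tested.

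With replicate number as a replicate block, SSZ1OEΔire1 against Δire1 had 289 calls, SSZ1OEΔire1Δscj1 against Δire1 2048 and SSZ1OEΔire1Δscj1 against SSZ1OEΔire1 597, with 165 shared rises and 65 shared falls, and 76 of the 334 gene calls ended, as did the list call of respiration in SSZ1OEΔire1Δscj1 against SSZ1OEΔire1 (adjusted p = 0.0729). Whether the numbers pair the samples was not settled. Across genes, deviations of same-numbered arrays had r of 0.15 and 0.11 between SSZ1OEΔire1 and Δire1. They had r of 0.11 and 0.00085 between SSZ1OEΔire1 and SSZ1OEΔire1Δscj1, and −0.037, −0.021 and 0.21 between Δire1 and SSZ1OEΔire1Δscj1. Deviations of the SSZ1OEΔire1 arrays mirror each other by construction, so their r values are not separate. Of the arrays of Δire1 and SSZ1OEΔire1Δscj1, 2 of 6 correlated best with their own number, as many as random numbering gives on average. List medians that turned sign with this replicate block were the Yap1 list −0.040, a-mating genes 0.038 and ribosomal proteins 0.012 in SSZ1OEΔire1 against Δire1. In SSZ1OEΔire1Δscj1 against SSZ1OEΔire1 they were Msn2/Msn4 genes 0.17, hexose transporters 0.019, phosphate genes 0.051 and histones −0.00086.

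Other splits of the 6 arrays of Δire1 and SSZ1OEΔire1Δscj1 called at most 0 genes by limma, against 2390 for the real split. Each other split mixes both strains within a group, so the difference between strains adds to the spread and few calls are left by construction. The contrast therefore decides nothing about the cause of the calls. With 10 splits, the real 1 included, they are too few for a share under 0.05.

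Medians of lists and values of genes turned sign as follows, each printed as it stood under the alternative. Spike-in scaling adds 1 shift to all genes by construction, and for the other settings the cause was not tested. In SSZ1OEΔire1 against Δire1 spike-in scaling turned ribosome-associated chaperones to 0.066, a-mating genes to 0.076 and ribosomal proteins to 0.081. In SSZ1OEΔire1Δscj1 against Δire1 it turned ribosome-associated chaperones to 0.059, Hsf1 targets to 0.40, the Yap1 list to 0.39, ergosterol genes to 0.21, phospholipid genes to 0.065, ribosome assembly to 0.071 and the methionine list to 0.021. It also turned phosphate genes to 0.17, nitrogen genes to 0.30, marker genes to 0.0069, haploid genes to 0.31, histones to 0.10, G1/S genes to 0.36 and translation factors to 0.025. Among genes it turned KAR2 to 0.27, EGD1 to 0.013, EGD2 to 0.059, SEC61 to 0.019 and HTB1 to 0.0096. In SSZ1OEΔire1Δscj1 against SSZ1OEΔire1 it turned UPR targets to 0.26, ER chaperones to 0.25, Msn2/Msn4 genes to 0.26, ergosterol genes to 0.28, phospholipid genes to 0.10, ribosome assembly to 0.30 and hexose transporters to 0.31. There it also turned respiration to 0.18, the tricarboxylic acid cycle to 0.19, phosphate genes to 0.26, purine and pyrimidine genes to 0.20, marker genes to 0.082, translation factors to 0.098 and HTB2 to 0.11.

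Quantile normalization turned the Yap1 list to −0.050, haploid genes to −0.011 and meiosis genes to −0.053 in SSZ1OEΔire1 against Δire1, and ER chaperones to −0.021 and Hsf1 targets to 0.0048 in SSZ1OEΔire1Δscj1 against Δire1. In SSZ1OEΔire1Δscj1 against SSZ1OEΔire1 it turned the Yap1 list to −0.041, ergosterol genes to 0.14, phospholipid genes to 0.011, ribosome assembly to 0.054 and glycolysis to 0.024, with SSZ1 at 0.073, ADH1 at 0.023, FBA1 at 0.028 and TEF1 at 0.019. Median scaling turned the Yap1 list to −0.059 and haploid genes to −0.024 in SSZ1OEΔire1 against Δire1. It turned UPR targets to −0.044, ER chaperones to −0.060, respiration to −0.068 and the tricarboxylic acid cycle to −0.094 in SSZ1OEΔire1Δscj1 against Δire1. Against SSZ1OEΔire1 it turned haploid genes to −0.027, histones to −0.036, G1/S genes to −0.020 and HAC1 to −0.031.

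Slide row as a block turned the Yap1 list to −0.019 in SSZ1OEΔire1 against Δire1, and Hsf1 targets to 0.037 and the tricarboxylic acid cycle to −0.080 in SSZ1OEΔire1Δscj1 against Δire1. Against SSZ1OEΔire1 it turned ER-associated degradation to −0.0095, Msn2/Msn4 genes to 0.0086, ribosome assembly to 0.030, hexose transporters to 0.16, phosphate genes to 0.14, histones to −0.041 and G1/S genes to −0.045. Array weights turned a-mating genes to 0.030, the tricarboxylic acid cycle to −0.14 and the Yap1 list to −0.023 in the 3 comparisons in order. Normexp turned alpha-mating genes to 0.00013 in SSZ1OEΔire1 against Δire1 and the Yap1 list to −0.046 against SSZ1OEΔire1. Among probes well above background on all 8 arrays, alpha-mating genes stood at 0.15 and haploid genes at −0.012 in SSZ1OEΔire1 against Δire1, and haploid genes at −0.059 in SSZ1OEΔire1Δscj1 against SSZ1OEΔire1. Without the filter hexose transporters stood at 0.039 in the latter comparison.

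Without single arrays, medians in SSZ1OEΔire1 against Δire1 ranged from −0.086 to 0.0075 for ribosome-associated chaperones, −0.019 to 0.0063 for the Yap1 list, −0.24 to 0.023 for the methionine list and −0.24 to 0.016 for marker genes. They ranged from −0.14 to 0.084 for a-mating genes, −0.047 to 0.23 for haploid genes, −0.20 to 0.021 for G2/M genes and −0.066 to 0.014 for ribosomal proteins. In SSZ1OEΔire1Δscj1 against Δire1 the ranges were −0.20 to 0.037 for Hsf1 targets, −0.083 to 0.0034 for the Yap1 list, −0.0070 to 0.088 for respiration and −0.14 to 0.078 for the tricarboxylic acid cycle. Against SSZ1OEΔire1 they were −0.015 to 0.092 for ER-associated degradation, −0.17 to 0.20 for Msn2/Msn4 genes, −0.10 to 0.080 for the Yap1 list, −0.044 to 0.053 for ergosterol genes, −0.039 to 0.020 for ribosome assembly and −0.024 to 0.030 for hexose transporters. There they were also −0.18 to 0.0010 for the tricarboxylic acid cycle, −0.056 to 0.021 for phosphate genes, −0.014 to 0.41 for nitrogen genes, −0.067 to 0.034 for haploid genes, −0.083 to 0.097 for histones and −0.050 to 0.069 for HAC1.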

Other observations

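The tests of scaling, of bright signals, of alpha cells and of the PHO84 locus in this part were chosen only after the result was seen. Genes near the ends of chromosomes were higher in SSZ1OEΔire1Δscj1. Of the last 10 listed genes at each end (assembly R64), 284 of 320 were tested, and 126 rose and 13 fell against Δire1. Their median log2 difference was 0.37, above every one of 10000 random lists of other genes matched on mean signal (median 0.077, highest 0.19). In SSZ1OEΔire1 the median was 0.11, with 48 rising and 4 falling (percentile 98.99 of matched lists), and SSZ1OEΔire1Δscj1 lay 0.17 above SSZ1OEΔire1 (highest matched list 0.092). No explanation of this was tested. The matched lists drew genes independently of each other, so they make no allowance for end genes that change together. Other scalings and slide row as a block were not run for it, and spike-in scaling would add 0.42 to all genes alike in the comparison with Δire1.

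HSP12, HSP26 and DDR2 had the widest spread among SSZ1OEΔire1Δscj1 arrays, and the genes of this paragraph were chosen after their values were seen. HSP12, a membrane-stabilising stress gene, stood at 0.23, 0.23 and −3.08 on replicates 1 to 3, HSP26, a small heat shock gene, at −1.82, 0.17 and −2.94, and DDR2 at −1.85, −0.11 and −3.14. In Δire1 these genes spanned −1.86 to −1.51 (HSP12), −2.55 to −2.15 (HSP26) and −2.83 to −2.49 (DDR2). CTT1, a stress gene under Msn2/Msn4 like HSP12 and DDR2, spanned only −3.03 to −2.32 in SSZ1OEΔire1Δscj1. LEU2, a leucine synthesis gene and common plasmid marker, stood at 0.48, −0.021 and 2.73 in Δire1 replicates 1 to 3, and between 2.12 and 2.46 on the other 5 arrays. The Δire1 arrays were thus not alike for this gene, and replicate 3 is the only Δire1 array of slide row 2. The labels do not give the markers of the strains, and whether this bears on the comparisons was not tested. The widest spread between the SSZ1OEΔire1 arrays was that of RRT7 (3.84), which stood at −4.17 and −8.01 on replicates 1 and 2.

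Ribosomal protein transcripts were lower in SSZ1OEΔire1Δscj1 than in Δire1 relative to the array's 75th percentile (median −0.44). Slide row alone is argued against: the highest SSZ1OEΔire1Δscj1 array differed by −0.27 from the Δire1 array of the same slide row, where the 3 Δire1 arrays spanned 0.020, although 1 Δire1 array bears on this. Spike-in scaling moves all genes of an array alike, so its median of −0.020 (shift 0.42, SE 0.20) decides nothing about a fall relative to other genes, which was −0.46 with it too. A loss of range among bright signals stays open. Quantile normalization left −0.11, or −0.049 relative to all genes, but it gives every array the same distribution. It would thus shrink a fall of many bright genes whatever its cause, and decides nothing here. The 10000 lists of other genes of like signal had a median of −0.34 and a lowest value of −0.44, and 0.03% of them lay below the ribosomal proteins. Against SSZ1OEΔire1 their median was −0.25 and the lowest −0.36, and the ribosomal proteins lay at −0.44. These lists drew genes independently of each other, so they make no allowance for genes that change together. The genotype remains a possible explanation that these tests cannot separate, and the brightest 624 genes had a median of −0.29, with 30 rising and 306 falling. Other lower lists of this comparison, such as glycolysis and translation factors, were not set against genes of like signal, so the same question stays open for them.

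STE3, MF(ALPHA)1 and AFB1, genes of alpha cells, were higher in SSZ1OEΔire1Δscj1. Background as the whole cause is argued against, since all were well above background on all 8 arrays and the smallest difference was 0.98 with normexp, although STE3 then differed by 2.23 in place of 3.07 and MF(ALPHA)1 by 1.31 in place of 2.08. Slide row is argued against, since the smallest difference was 0.93 with that block, although only 1 Δire1 array bears on this. Alpha cells in the cultures would raise their other transcripts too, and 1 of 4 rose: HMLALPHA2 (0.60, adjusted p = 0.0481) did, while HMLALPHA1 (0.15), SAG1 (0.15) and MF(ALPHA)2 (−0.42) did not pass. MATALPHA2 (0.59, limma adjusted p = 0.0542) and MATALPHA1 (0.12, adjusted p = 0.622) were tested but not counted, and did not pass. HMLALPHA2 and MATALPHA2 thus lay on either side of the threshold with like values. The fall of 6 of 7 a-mating genes (median −0.72) goes with alpha cells, while no a-mating gene was called by limma in SSZ1OEΔire1, where STE3 also rose, and the genotype stays open as untested, with the mating type of the parent strain not given in the sources used here.

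PHO84 was lower in both overexpressing strains. A change at its locus alone is argued against, since 4 of the 17 other phosphate genes (PHO5, SPL2, VTC3 and VTC4) also fell in both. Slide row is argued against as well, since with that block PHO84 differed by −5.96 and −4.36 and the larger adjusted p was 0.00184. For SSZ1OEΔire1Δscj1, however, only Δire1 replicate 3, the Δire1 array of the same slide row, bears on this. Phosphate supply in the cultures and the genotype stay open as untested.

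Deletion of SCJ1 could have disturbed its neighbours, and 0 of 2 passed limma's test in both comparisons of SSZ1OEΔire1Δscj1. CEF1 differed by 0.039 from Δire1 (adjusted p = 0.691), and GAS3 by −0.46 (adjusted p = 0.0498), but GAS3 differed by −0.36 from SSZ1OEΔire1 (adjusted p = 0.201).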
